A study of Mus musculus with 24 samples.

How the data were processed

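Total RNA of mouse liver was extracted with Trizol, treated with DNase, depleted of ribosomal RNA and made into libraries with a TruSeq RNA kit, then sequenced on a HiSeq2500, per the labels' protocols. The kit as named does not mark the strand of a transcript, but the counts leave open whether these libraries do. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0, HTSeq 0.11.2 and the mm10 build were used. The annotation, the strand setting of the counting and any filters are not given in the sources used here. The series table holds raw counts per gene as deposited, for 24421 gene symbols with 0 duplicated symbols and 0 entries that name no gene. Of these, 8880 had 0 counts in all 24 libraries and 15541 had at least 1 count, 8606009 counts in all. The per-sample files hold log2 values as deposited, which were checked to equal log2(count / size factor + 1), with 0 values differing by over 1e-06. Their size factors equal median-of-ratios factors over the 270 genes above 0 in every library, with a largest relative difference of 4.22e-15. All tests used the counts.

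The third w12_WD library held 607 counts, and the other libraries held 126160 to 962493. The other libraries had counts for 6119 to 12173 genes, and the pair of entries with most counts, Gm30505 and Gm10069, took 10.51% to 24.99% of them. A 0 was read as an upper limit of 3 counts, and ratios with 1 to 3 counts in a group have exact 95% intervals. These limits and intervals cover counting error only. Where a group had 0 counts, a lower bound of the fold was taken against a floor of 3 counts over the group. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom from 3.13 to 12.01 and 0 identical pairs, so every library was counted once.

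Symbols were matched to the GENCODE M21 annotation of GRCm38, 23376 by symbol and 668 by a RefSeq synonym. Some symbols matched more than 1 gene and were not placed. Exons that overlap a gene on the other strand were found with bedtools 2.31.1. This gave 5800 entries with such an overlap, 18202 without and 419 not placed. Of all entries, 98.28% were placed, each on exactly 1 gene.

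Counts were filtered with edgeR's expression filter and scaled with TMM, which left 4198 genes, 2123 with an overlap, 2028 without and 47 not placed. One quasi-likelihood model of edgeR 4.0.16 with the 8 groups was fitted in R 4.3.3 to the 24 libraries, with a common biological coefficient of variation of 0.317. There were 13 comparisons, each with Benjamini-Hochberg adjustment and a threshold of 0.05. They were the diet effect and the VC effect in each of the other conditions, the diet by VC interaction at each time, the time effect on control diet, and diet by time and VC by time interactions. The groups, tests, named-gene rule and 39 gene lists were chosen before the data were examined. Lists with at least 3 tested members, 26 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over lists within a comparison.

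Named genes were up to 6 per direction with the largest log2 fold change past the threshold, a mean of at least 1 CPM in a group, groups that did not overlap, and no predicted or clone symbol. For 3 libraries against 3, chance gives such separation for 10% of genes. Up to 4 members with the smallest adjusted p were added from each called list, and where fewer than 5 genes passed, the 5 with the smallest p were taken as values. Cyp2e1, Mettl3, Fto, Alkbh5, Ythdf2, Afp, Gpc3 and Mki67 were always included. Interactions had no overlap condition. Values are given for a selection of these genes, made after the values were seen, and 1 gene is not reported here.

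The gene test was tried on simulated counts with 200 genes changed, and the list test with 5 lists raised. In comparisons of 2 groups, 74.2% to 90.9% of 8-fold, 43.3% to 64.2% of 4-fold and 6% to 19.4% of 2-fold changes were recovered, and in interactions 57.6% to 60.6%, 19.4% to 29.9% and 1.5% to 3%. Calls among the unchanged genes numbered 2 to 8 in comparisons of 2 groups, with 7 for diet with VC at 12 weeks and 8 for VC on Western diet at 12 months, and 1 to 5 in interactions. In the simulation of VC on control diet at 12 months, 5 of 5 lists raised 2-fold were called, also with an estimated correlation, and 0 of 19 others. Its genes were drawn independently and without a shift of no-overlap entries. It therefore cannot show how the list test fares with correlated genes or with such a shift. Alternatives were RLE size factors, no expression filter, DESeq2 1.42.0, limma-voom with quality weights, fits of the compared groups or of the same time alone, the replicate number as a block, and leaving out each library. Class-wise TMM scaling, tests of entries without an overlap alone and a fit of 23 libraries without the smallest were chosen after seeing the data. So were the thinning of larger libraries to 126160 counts in 20 draws, and a permutation test of macrophage against endothelial and stellate markers with 100000 permutations. An exact sign-flip test of log2 count ratios between liver genes and their partner entries, and the coefficient of variation within splits, were also chosen then. Tables were handled in Python 3.11.15 with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.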

Results

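Liver RNA of male C57Bl/6J mice was sequenced after a control diet (13% fat) or a Western diet (42% fat), each with inhaled vinyl chloride (VC) or clean air. VC is an industrial monomer that the liver oxidises, and its nominal concentration was 0.85 ± 0.1 ppm, below the workplace limit, for 6 hours a day on 5 days a week over 12 weeks. Groups named w12 were taken at the end of those 12 weeks, and groups named m12 after 9 further months of housing. CD and WD stand for the diets, +VC for the exposure, and each of the 8 groups held 3 libraries. The design asks how diet, transient exposure and time act on the liver transcriptome, alone and in combination. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples. Values below are mean CPM ± SD (n = 3), and coordinates are from GRCm38 (mm10).

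The libraries were shallow. Of the 24, 23 held 126160 to 962493 counts, with a median of 379638 over all libraries, and w12_WD 3 held 607. A count of 0 allows up to 3.12 to 23.78 CPM in the 23 libraries. Totals ran from 258401 to 399052 in w12_CD, 140926 to 421344 in w12_CD+VC, 607 to 420735 in w12_WD and 152082 to 566870 in w12_WD+VC. At 12 months they ran from 332126 to 470374 in m12_CD, 126160 to 384262 in m12_CD+VC, 407177 to 962493 in m12_WD and 141457 to 640952 in m12_WD+VC. Gene entries whose exons overlap a gene on the other strand made up 23.75% of the table and held 78.57% of the counts, while entries without such an overlap held 19.74%. The latter share differed between groups at 12 months, where it was 15.6% ± 3.56 in m12_CD, 26.6% ± 4.63 in m12_CD+VC, 25.9% ± 3.89 in m12_WD and 20.7% ± 2.41 in m12_WD+VC (SD, n = 3). At 12 weeks it lay between 16.0% ± 2.79 in w12_WD and 17.1% ± 2.51 in w12_CD+VC. Reads of overlapping or antisense genes, and of paralogs such as the Mup, Serpina1, Orm, Cyp and Gst families, cannot be assigned with certainty, and values of those genes are uncertain. The strand setting of the counting is not given in the sources used here, and it stays open whether entries hold reads of their own strand. Of the 30 entries with most counts 25 overlap a gene on the other strand, the first of them Gm30505 with 811098 counts against 9493 for its partner, the liver-secreted glycoprotein gene Ahsg. The doubt covers every entry, with or without an overlap, and gene names below stand for entries of the deposited table.

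**Figure D1:**
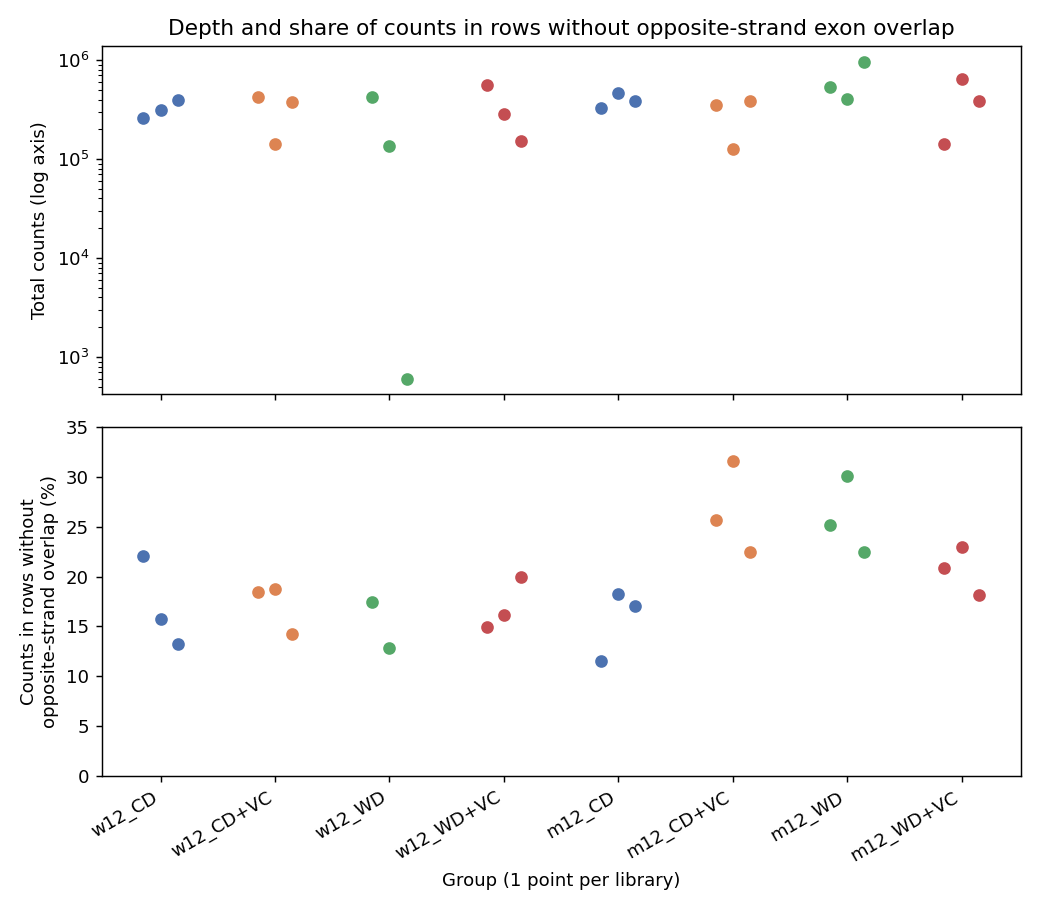
Total counts of each of the 24 libraries by group (upper panel, log axis) and the percent of those counts in gene entries without an opposite-strand exon overlap (lower panel, the 23 larger libraries). Each point is 1 library. Library w12_WD 3 stands at 607 counts, and the lower panel runs from 11.56% to 31.63%, with m12_CD+VC and m12_WD above m12_CD.

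Of 4198 genes tested with edgeR, the comparisons called between 0 and 1028 at an adjusted p of 0.05. Chance would put about 210 genes at an unadjusted p under 0.05. Of 26 gene lists tested, 15 were called by camera in at least 1 of the 13 comparisons, always with a preset correlation of 0.01. None of the 72 list calls held with an estimated correlation, where the lowest adjusted p was 0.309. No called gene named here and no called list turned direction under RLE, class-wise or DESeq2 scaling where these were run. RLE scaling shifted the median log2 fold change of all genes by 0.39 for diet without VC, 0.417 for VC on control diet, -0.126 for diet with VC and -0.516 for the interaction at 12 months. It shifted it by -0.129 for time, 0.373 for diet by time and -0.111 for VC by time. Changes are relative to the TMM-scaled bulk of genes.

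**Figure D2:**
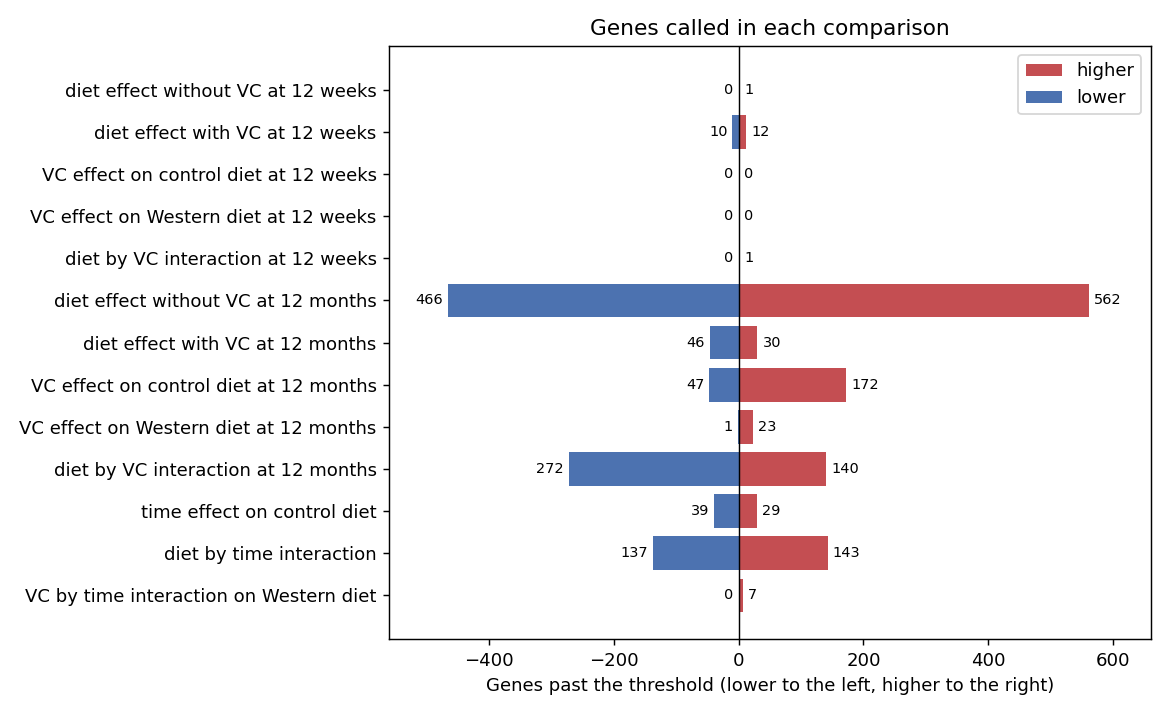
Number of genes past the threshold of adjusted p 0.05 in each of the 13 comparisons, lower to the left and higher to the right. The diet effect without VC at 12 months has the longest bars, with 562 genes higher and 466 lower, and the VC effects at 12 weeks have 0.

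At 12 months without VC, Western diet livers had higher values than control livers for macrophage markers and for genes of fatty acid oxidation, xenobiotic metabolism and the acute phase. Of 10 tested macrophage and Kupffer cell genes, 6 rose over all genes and 9 adjusted over the list alone, with a median log2 change of 2.03 (camera adjusted p = 0.000529; 0.542 with an estimated correlation). The 12 tested endothelial and stellate markers had a median log2 change of 1.02, with 10 above 0, though neither of their lists was called. Lysozyme Lyz2 stood at 132 ± 102 CPM against 3.34 ± 0.979 from 3 counts, a ratio of 33 (95% counting interval 11.1 to 161). Gpnmb, a glycoprotein of lipid-laden macrophages, was at least 11.9-fold higher (37.5 ± 3.64 CPM, 0 counts in controls, edgeR adjusted p = 0.000785). The complement gene C1qa rose 5.09-fold to 98.9 ± 25.2 CPM (edgeR adjusted p = 0.00148) and Cd5l 10.4-fold (0.000724). Cathepsin S Ctss was at least 16.5-fold higher, the MHC class II gene H2-Aa at least 19.9-fold and lipoprotein lipase Lpl at least 22.7-fold, each with 0 counts in controls.

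Fatty acid oxidation and PPAR-alpha target genes rose in the same comparison, with 13 of 16 past the gene test and 14 adjusted over the list alone (camera adjusted p = 1.78e-05; 0.542 with an estimated correlation). The peroxisomal enzyme Ehhadh rose 9.32-fold, from 12.6 ± 12.8 to 129 ± 44.6 CPM (edgeR adjusted p = 9.92e-05), Cyp4a10 10.8-fold and Ppara itself 8.5-fold. Among xenobiotic P450s 4 of 11 rose, and 5 adjusted over the list alone (camera 0.0067; 0.542 with an estimated correlation), led by Cyp3a11 with 343 ± 50.9 against 33.3 ± 23.7 CPM (9.51-fold, edgeR adjusted p = 3.13e-05). The list of VC metabolism and glutathione conjugation had 11 of 18 members higher and 1 lower, also adjusted over the list alone (camera 0.00314; 0.620 with an estimated correlation). Aldh1a1 rose 4.84-fold and epoxide hydrolase Ephx1 5.65-fold. The member that fell, glutathione synthetase Gss (7.12-fold, edgeR adjusted p = 0.000227), overlaps Acss2 on the other strand. Cyp2e1, the P450 that oxidises VC (chromosome 7, 140763739 to 140774987), stood at 1760 ± 581 against 603 ± 325 CPM (2.89-fold, edgeR adjusted p = 0.0111), and lost the call without m12_CD 1 (0.0977) or m12_WD 1 (0.0598).

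The acute-phase, stress response, hepatocyte and NRF2 lists were also called as higher. Of 12 acute-phase genes 5 rose, and 8 adjusted over the list alone (camera 0.00248; 0.542 with an estimated correlation), with haptoglobin Hp at 3220 ± 421 against 787 ± 196 CPM (4.08-fold, edgeR adjusted p = 0.000148) and lipocalin Lcn2 9.46-fold higher. In the unfolded protein and integrated stress response 6 of 14 rose, and 9 adjusted over the list alone (camera 0.0067; 0.542 with an estimated correlation), with the chaperone Calr 2.52-fold higher. For hepatocyte genes the numbers were 4 of 16 and again 4 adjusted over the list alone (camera 0.00234; 0.626 with an estimated correlation), including hemopexin Hpx (6.13-fold) and transferrin Trf (3.31-fold). Of 8 NRF2 targets 4 rose, the same number adjusted over the list alone (camera 0.0197; 0.577 with an estimated correlation), among them the iron-storing ferritin chains Fth1 (3.51-fold) and Ftl1 (3.02-fold). The hepatocyte call was lost without m12_CD 1 (0.0651) and with class-wise scaling (0.102), and the NRF2 call without m12_WD 1 (0.0572) or m12_WD 2 (0.073), with class-wise scaling (0.0579) and with RLE (0.0588).

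Genes that fell on Western diet included the chemokine-scavenging receptor Ackr2, at least 29-fold lower than the 45 ± 10.5 CPM of controls (edgeR adjusted p = 2.76e-05), and the urinary protein genes Mup11 and Mup14, at least 21.4-fold and 11.7-fold lower. Zap70, a T-cell kinase, had 3 counts against 58, a control-to-Western ratio of 39.3 (12.8 to 196). The antisense RNA AV064505 (chromosome 9, 7669429 to 7695631), which overlaps Mmp7, stood at 192 ± 49.7 CPM against a single count, a ratio of 174 (31 to 6880). Of the 44 called genes that the naming rule gives for this comparison, 34 kept the call whichever library was left out. The other 10, Atf4, Cyp2a4, Cyp2e1, Gstm1, Hsp90b1, Manf, Orm1, Orm3, Osgin1 and Por, lost it without at least 1 of m12_CD 1, m12_CD 2, m12_CD 3, m12_WD 1 or m12_WD 2 (edgeR adjusted p 0.0502 to 0.186). Class-wise scaling kept 41 of the 44, and no-overlap genes tested alone 28 of 34, with Cyp2e1 (0.097), Calr (0.104) and Trf (0.0507) among those lost. In all, 1028 genes were called, 562 higher and 466 lower. The no-overlap share of counts was 25.9% ± 3.89 against 15.6% ± 3.56, and the median log2 change was 0.475 in genes without an overlap and -0.159 in genes with one. Scaling moved the split of directions to 915 higher and 253 lower with RLE, 562 and 169 with DESeq2 and 440 and 478 with class-wise scaling. Without m12_CD 1 there were 632 calls, in a fit of the compared groups alone 610, and among no-overlap genes alone 370.

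With VC, the diet effect at 12 months included lower values for genes of lipid synthesis and for the hepatocyte list (m12_WD+VC against m12_CD+VC). Of 17 fatty acid and triglyceride synthesis genes 6 fell, and 13 adjusted over the list alone, with a median log2 change of -2.00 (camera adjusted p = 2.25e-11; 0.337 with an estimated correlation). The desaturase Fads2 stood at 136 ± 24.1 against 530 ± 154 CPM (3.99-fold lower, edgeR adjusted p = 0.00253), Fads1 was 4.25-fold lower and Acly, which makes cytosolic acetyl-CoA, 8.91-fold lower. Acss2, 9.24-fold lower, overlaps Gss. In cholesterol biosynthesis 3 of 13 fell and 1 rose, or 8 and 2 adjusted over the list alone (camera 0.00485; 0.38 with an estimated correlation). The sterol sensor gene Insig1 was 12.1-fold lower (5.14 ± 5.5 against 75.2 ± 17.6 CPM, edgeR adjusted p = 0.011), while squalene synthase Fdft1, which overlaps Ctsb, was 2.17-fold higher.

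The hepatocyte list was called as lower in that comparison, with 2 of 16 members past the gene test over all genes and 9 adjusted over the list alone (camera 8.18e-09; 0.38 with an estimated correlation). Albumin Alb (chromosome 5, 90460897 to 90476602) stood at 2560 ± 583 against 13000 ± 4670 CPM (5.05-fold lower, edgeR adjusted p = 0.00253), and the gluconeogenic Pck1 was 3.25-fold lower. Of 10 male-biased liver genes 1 fell, and 5 adjusted over the list alone (camera 3.67e-05; 0.337 with an estimated correlation), with Serpina1e 10.1-fold lower. Of 10 macrophage markers 1 rose, and 2 adjusted over the list alone (camera 0.0109; 0.478 with an estimated correlation), with C1qc at 133 ± 26.5 against 37.9 ± 18.4 CPM (3.24-fold, edgeR adjusted p = 0.0316). This call was lost without m12_CD+VC 3 (0.0684) or m12_WD+VC 2 (0.188). Galectin-3 Lgals3 stood at 29.2 ± 12.3 CPM against 1 count, a ratio of 29.3 (4.97 to 1190). The m12_CD+VC libraries also enter the VC effect on control diet, so lower values here and higher values there are not independent findings. Alb took 1.331% ± 0.562 of counts in m12_CD+VC and 0.253% ± 0.072 in m12_WD+VC. It took 0.313% ± 0.189 in m12_CD and 0.558% ± 0.268 in m12_WD (SD, n = 3).

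Other lists were also called as lower with Western diet under VC. Glucose metabolism had 1 of 11 lower and 3 adjusted over the list alone (camera 0.00086; 0.467 with an estimated correlation), and VC metabolism and glutathione conjugation 0 of 18 and 2 (5.17e-05; 0.467 with an estimated correlation). The nuclear-encoded respiratory chain had 0 of 20 and 2 adjusted over the list alone (camera 0.00572; 0.602 with an estimated correlation), lost without m12_CD+VC 2 (0.0636). Fatty acid oxidation had 1 of 16 in both counts (camera 0.0235; 0.665 with an estimated correlation). It was lost without m12_CD+VC 2 (0.187) or m12_WD+VC 3 (0.139). Bile acid and sterol handling had 0 of 17 in both counts (camera 0.0321; 0.598 with an estimated correlation), lost without m12_CD+VC 2 (0.184), m12_WD+VC 1 (0.0641) or m12_WD+VC 3 (0.0673). Class-wise scaling ended these last calls as well, at 0.0723 and 0.105, as did RLE, at 0.0507 and 0.068.

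This comparison called 76 genes, 30 higher and 46 lower. The no-overlap share of counts was 20.7% ± 2.41 against 26.6% ± 4.63, and the median log2 change was -0.229 in genes without an overlap and 0.164 in genes with one. Without m12_WD+VC 2 only 2 calls were left, and Alb and AV064505 were the 2 named genes called whichever library was left out. RLE kept 16 of the 23 named calls, with Acly and C1qc (0.0674 each) among those lost, and DESeq2 13 of the 18 with a value, with Acly (0.108), Acss2 (0.0704) and C1qc (0.146) among those lost. Fdft1 lost the call without an expression filter (0.0774), and Pck1 among no-overlap genes alone (0.0855). Leaving out m12_CD+VC 2 gave 25, m12_CD+VC 3 gave 32, m12_WD+VC 1 gave 36 and m12_WD+VC 3 gave 35. The split was 13 higher and 33 lower with RLE and 11 and 33 with DESeq2, while limma-voom called 159 and a fit of the compared groups alone 158. Among the 1028 and the 76 diet calls, 18 genes were higher in both comparisons against 4.02 expected for independent lists, and 21 lower in both against 5.11. That expectation takes every gene as equally likely to be called. Across all tested genes the log2 changes of the diet effects without and with VC correlated at 0.174 (Pearson) and 0.028 (Spearman).

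On control diet, livers 9 months after VC had higher values than unexposed livers for hepatocyte, VC-metabolising and fatty acid oxidation genes (m12_CD+VC against m12_CD). Of 16 hepatocyte genes 6 rose, and 13 adjusted over the list alone (camera adjusted p = 4.16e-09; 0.368 with an estimated correlation), with Alb at 13000 ± 4670 against 3800 ± 2120 CPM (3.4-fold, edgeR adjusted p = 0.0147). Of 18 genes of VC metabolism and glutathione conjugation 9 rose, and 13 adjusted over the list alone (camera 1.85e-07; 0.368 with an estimated correlation). Aldh1a1 stood at 252 ± 115 against 35.2 ± 25 CPM (6.45-fold, edgeR adjusted p = 0.00579), the glutathione transferase Gstp1 was 7.82-fold higher and Mgst1 4.28-fold. Cyp2e1 was 2.91-fold higher (1780 ± 1320 against 603 ± 325 CPM, edgeR adjusted p = 0.0411). In fatty acid oxidation 8 of 16 rose, and 10 adjusted over the list alone (camera 8.7e-07; 0.368 with an estimated correlation), including the mitochondrial carnitine transferase Cpt1a (2.96-fold) and Ehhadh (5.9-fold).

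Other lists were also called as higher with VC on control diet. NRF2 targets had 4 of 8 higher and 5 adjusted over the list alone (camera 0.000232; 0.368 with an estimated correlation), and male-biased genes 4 of 10 in both counts (0.00369; 0.451 with an estimated correlation), including Serpina1e and Mup20, 7.71-fold and 5.4-fold higher. The respiratory chain had 1 of 20 and 2 adjusted over the list alone (camera 0.00261; 0.481 with an estimated correlation), with the ATP synthase subunit Atp5b 3.73-fold higher (edgeR adjusted p = 0.00654). Fatty acid and triglyceride synthesis had 1 of 17 in both counts, the acyltransferase Gpam (camera 0.00116; 0.481 with an estimated correlation). Xenobiotic P450s had 3 of 11 and 6 adjusted over the list alone (camera 0.0255; 0.481 with an estimated correlation), with Cyp1a2 6.6-fold higher, and were lost without m12_CD 1 (0.11) and with RLE (0.0521). Glucose metabolism had 1 of 11 and 3, led by lactate dehydrogenase Ldha (camera 0.00257; 0.481 with an estimated correlation), lost without m12_CD 1 (0.0537). The stress response had 1 of 14 and 4, led by Xbp1 (camera 0.0361; 0.483 with an estimated correlation), lost without m12_CD 3 (0.0926), m12_CD+VC 1 (0.0914) or m12_CD+VC 2 (0.104). Acute-phase genes had 1 of 12 and 2, led by Orm1 (camera 0.0269; 0.483 with an estimated correlation), lost without m12_CD 3 (0.115), m12_CD+VC 2 (0.0538) or m12_CD+VC 3 (0.129), with class-wise scaling (0.156) and with RLE (0.0605).

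Single genes changed by VC on control diet included the lysosomal mannosidase Man2b1, at 39.8 ± 10.6 CPM against 2 counts (ratio 18.3, 4.69 to 158), and the chaperone Hsph1, at least 9.97-fold higher. The cation transporter Slc22a3 was 5.45-fold lower (34.8 ± 4.75 against 198 ± 145 CPM, edgeR adjusted p = 0.0158) and overlaps Plg. In all, 219 genes were called, 172 higher and 47 lower. Among genes without an overlap 133 were higher and 8 lower, and among genes with one 39 and 38. The no-overlap share was 26.6% ± 4.63 with VC against 15.6% ± 3.56 without, and the median log2 change was 0.58 in genes without an overlap and -0.299 in genes with one. The same m12_CD libraries serve as reference for the diet effect without VC, and the m12_CD+VC libraries as reference for the diet effect with VC. No gene was called without m12_CD 1, nor without m12_CD+VC 2, against 139 without m12_CD 3, 94 without m12_CD+VC 1 and 346 without m12_CD+VC 3, of which 170 were higher and 176 lower. Libraries m12_CD 1 and m12_CD+VC 2 had the lowest and the highest no-overlap share of all libraries, 11.56% and 31.63%, and Alb took 0.094% and 1.947% of their counts. The split was 434 higher and 8 lower with RLE, 249 and 0 with DESeq2 and 128 and 81 in 23 libraries, and class-wise scaling called 107, 74 of them higher. No-overlap genes tested alone gave 18 calls, 10 higher and 8 lower. Class-wise scaling kept 18 of the 40 named calls and ended those of Alb (0.0587), Cyp2e1 (0.143) and Cpt1a (0.0868) among others, and the test of no-overlap genes alone kept 7 of 29.

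On Western diet, 24 genes differed at 12 months with VC (m12_WD+VC against m12_WD), 23 of them higher. The antisense RNA Zfhx2os (chromosome 14, 55053869 to 55075873), which overlaps Zfhx2, stood at 262 ± 107 against 29.9 ± 7.21 CPM (8.2-fold, edgeR adjusted p = 7.52e-06). Zfp668 stood at 40.3 ± 23.2 CPM against 1 count (ratio 59.6, 10 to 2420) and overlaps Zfp646, and Lrfn4 was 5.17-fold higher (edgeR adjusted p = 0.00149). These 3 kept the call whichever library was left out, while limma-voom kept 3 of the 7 named calls and ended that of Zfp668 (0.056). The Notch coactivator Maml1 was 5.34-fold higher, lost without any of 5 libraries (adjusted p 0.0511 to 0.139, kept without m12_WD 1). The immunoglobulin transporter Pigr was 2.44-fold lower (1070 ± 130 against 2610 ± 584 CPM, edgeR adjusted p = 0.0317), lost without any of 5 libraries (0.0701 to 0.239, kept without m12_WD 2). The fatty acid oxidation and hepatocyte lists were called as lower, each with 0 of 16 members past the gene test in both counts (camera adjusted p = 8.57e-05 for each; 0.742 with an estimated correlation). So was VC metabolism and glutathione conjugation, with 0 of 18 in both counts (camera 0.0366; 0.742 with an estimated correlation), lost without m12_WD 1 (0.247), m12_WD 2 (0.33) or m12_WD+VC 1 (0.0521), with class-wise scaling (0.0824) and with RLE (0.0769). The no-overlap share was 20.7% ± 2.41 against 25.9% ± 3.89. Counts fell to 10 without m12_WD+VC 3, 14 without m12_WD 3 and 15 without m12_WD+VC 1, and a fit of the 12-month groups alone called 10.

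The diet effect differed with and without VC at 12 months for 412 genes, 140 with a more positive and 272 with a more negative diet effect under VC. Zfp668 stood at 34.9 ± 14.9 CPM in m12_CD, 28.6 ± 11.1 in m12_CD+VC, 0.63 ± 1.09 in m12_WD and 40.3 ± 23.2 in m12_WD+VC (edgeR adjusted p = 0.00292). The ribosomal protein gene Rps4x stood at 3.59 ± 3.27, 39.1 ± 37.1, 75.8 ± 66.4 and 16.6 ± 5.67 CPM in the same order (edgeR adjusted p = 0.00741), and Cdc27, part of the anaphase-promoting complex, at 36 ± 16.6, 18.8 ± 16.2, 1.26 ± 2.18 and 12.6 ± 2.03 (0.0176). These 3 kept the call without each library. DESeq2 kept Zfp668 and Rps4x, gave no adjusted p for Cdc27, and kept 2 of the 4 named calls with a value, against 7 of 12 with limma-voom and 8 of 12 with class-wise scaling. Lpl stood at 0, 12 ± 12.5, 71.6 ± 30.8 and 31.8 ± 13.6 CPM (edgeR adjusted p = 0.0255), lost without m12_CD 1 (0.0588), m12_CD+VC 1 (0.0858), m12_WD 2 (0.0535) or m12_WD+VC 3 (0.0703) and with class-wise scaling (0.0503).

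Several lists had a more negative diet effect under VC. Hepatocyte genes had 8 of 16 past the gene test and 14 adjusted over the list alone (camera 1.06e-09; 0.398 with an estimated correlation), fatty acid oxidation 10 of 16 and 13 (4.13e-08; 0.398), VC metabolism and glutathione conjugation 9 of 18 and 11 (4.34e-07; 0.398). With an estimated correlation the adjusted p was 0.434 for each of the others. These were glucose metabolism with 4 of 11 and 5 adjusted over the list alone (camera 0.00114), the respiratory chain with 3 of 20 and 6 (0.00166), NRF2 targets with 3 of 8 and 4 (0.00183), fatty acid and triglyceride synthesis with 0 of 17 in both counts (0.00195) and xenobiotic P450s with 4 of 11 and 7 (0.00473). The stress response had 0 of 14 in both counts (camera 0.0256), acute-phase genes 2 of 12 in both counts (0.0289) and macrophage genes 2 of 10 and 3 (0.0428). The macrophage call was lost without m12_CD 2 (0.0893), m12_CD 3 (0.0542) or m12_CD+VC 1 (0.098), with class-wise scaling (0.129) and with RLE (0.0955), and the stress call without m12_CD 3 (0.0542), m12_CD+VC 1 (0.05), m12_WD 2 (0.0551) or m12_WD+VC 3 (0.0917). The acute-phase call was lost without m12_CD 3 (0.089), m12_CD+VC 3 (0.0765), m12_WD 2 (0.0572) or m12_WD+VC 3 (0.127) and with class-wise scaling (0.257). Median log2 differences were -0.728 in genes without an overlap and 0.417 in genes with one, beside no-overlap shares of 15.6%, 26.6%, 25.9% and 20.7% in the order used here. The count was 152 without m12_CD 1, 140 without m12_CD+VC 2, 178 without m12_WD 2, 99 without m12_WD+VC 3 and 644 without m12_WD 3. More positive and more negative genes numbered 39 and 481 with RLE, 11 and 241 with DESeq2, 112 and 139 with class-wise scaling and 180 and 223 in 23 libraries.

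**Figure D3:**
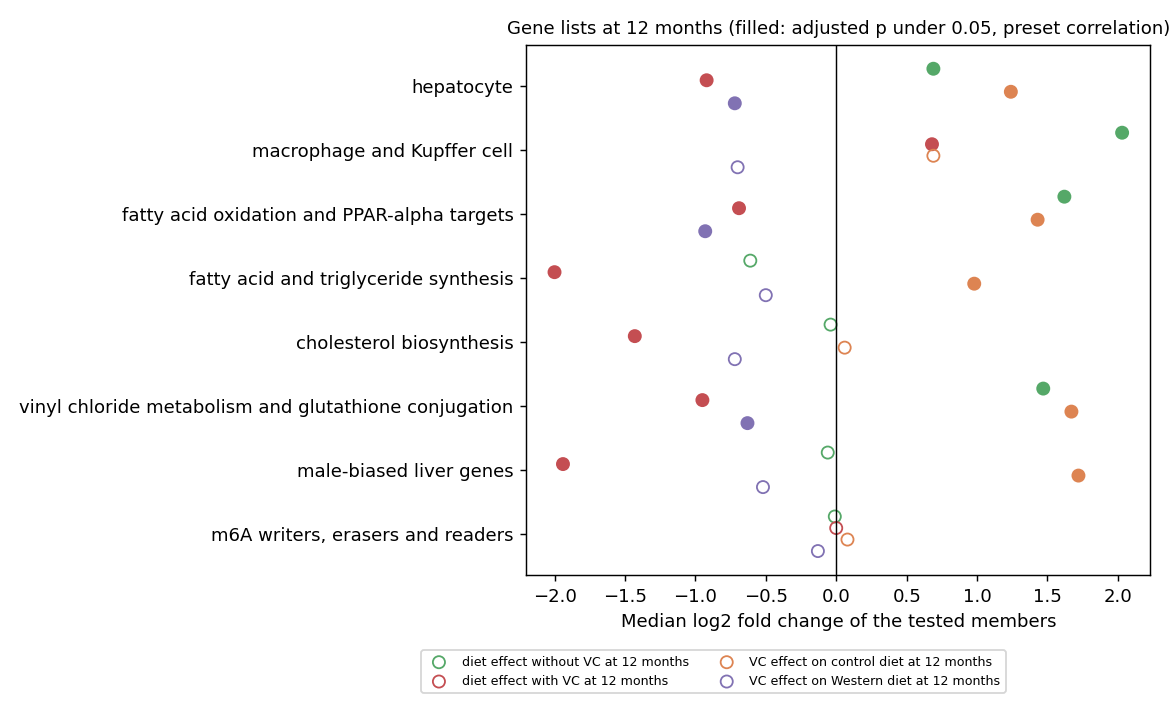
Median fitted log2 fold change of the tested members of 8 gene lists in the 4 comparisons of 2 groups at 12 months. Each circle is 1 list in 1 comparison, filled where the camera adjusted p with the preset correlation is under 0.05. Fatty acid and triglyceride synthesis stands at -2.00 for diet with VC, and the macrophage list at 2.03 for diet without VC.

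At the end of exposure, Western diet changed 22 genes in VC-exposed livers, 12 higher and 10 lower (w12_WD+VC against w12_CD+VC). The redox regulator Txnip, which overlaps Gm15441, stood at 1010 ± 840 against 36.5 ± 31.9 CPM (26-fold, edgeR adjusted p = 0.00385). The fatty acid hydroxylase Cyp4a14 stood at 81.8 ± 31.3 CPM against 2 counts (ratio 37.2, 9.94 to 312) and the peroxisomal thioesterase Acot4 was at least 8.1-fold higher. Tor1a was 8.1-fold higher, and the ephrin Efna3 24.4-fold and Slc22a3 5.9-fold lower. The fatty acid oxidation list was called as higher, with 1 of 16 members past the gene test over all genes and 2 adjusted over the list alone (camera 0.000534; 0.786 with an estimated correlation), lost without w12_CD+VC 3 (0.063). Male-biased genes were called as lower as a list, with 0 of 10 and 1 adjusted over the list alone (camera 8.04e-05; 0.635 with an estimated correlation). For the hepatocyte list, also called as lower, 0 of 16 members passed in both counts (camera 0.0255; 0.786 with an estimated correlation), lost without w12_CD+VC 1 (0.124), w12_CD+VC 2 (0.209), w12_WD+VC 1 (0.105) or w12_WD+VC 2 (0.094) and with RLE (0.0694). No gene was called without w12_WD+VC 1, where Txnip stood at an adjusted p of 0.138. RLE kept 8 of the 12 named calls, with Cyp4a14 and Acot4 (0.0577 each) and Slc22a3 (0.0528) among those lost, and limma-voom kept 7. Leaving out w12_CD+VC 1, 2 or 3 gave 10, 6 or 5 calls, w12_WD+VC 2 gave 12 and w12_WD+VC 3 gave 42. Class-wise scaling called 12 higher and 6 lower.

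Without VC, the diet effect at 12 weeks rested on w12_WD, which includes the 607-count library, and edgeR called 1 gene. Ccdc85b, which overlaps Fosl1, stood at 42.2 ± 52.5 CPM, or 63.3 ± 53.4 in the larger libraries (n = 2), against 1 count (ratio 68.8, 11.7 to 2780; edgeR adjusted p = 0.0233). It was lost without w12_CD 1 (0.141), w12_CD 2 (0.188), w12_CD 3 (0.0904) or w12_WD 1 (0.598). Dlec1, which overlaps Acaa1b, stood at 260 ± 64.3 CPM in the larger libraries against 30.7 ± 11.6 and did not pass (edgeR adjusted p = 0.145), nor did Fkbp3 with 59.7 ± 36.4 against 283 ± 32 (0.145). Unadjusted, 237 genes lay under 0.05, and the single call was kept in 23 libraries while DESeq2 called 0. Without an expression filter, with limma-voom and in a fit of the compared groups alone there were 6 calls each. The hepatocyte list was called as lower with 0 of 16 members past the gene test in both counts (camera 4.55e-05; 0.960 with an estimated correlation), lost without w12_CD 1 (0.161) or w12_WD 2 (0.824). The male-biased list was called as lower with 0 of 10 and 1 adjusted over the list alone (camera 0.0107; 0.960 with an estimated correlation), lost without w12_CD 1 (0.161) or w12_WD 2 (0.0749).

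VC on control diet gave no called gene at 12 weeks with edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 there were 170 genes with edgeR and 71 with DESeq2. The glutathione transferase Gstt2 had the smallest p, with 3.49 ± 4.01 CPM from 2 counts against 39.5 ± 6.9, and did not pass (edgeR adjusted p = 0.0567). Fam20c stood at 221 ± 95.9 against 86.1 ± 6.06 CPM (0.468) and Ginm1, which overlaps B430219N15Rik, at 73.2 ± 32.5 against 14.6 ± 1.3 (0.727). No list was called. In simulated data for this comparison 78.8% of 8-fold, 52.2% of 4-fold and 6% of 2-fold changes were recovered. There was 1 call without w12_CD+VC 2, 1 with class-wise scaling, 1 among no-overlap genes alone and 5 without an expression filter.

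VC on Western diet also gave no called gene at 12 weeks with edgeR in the model of all groups, against 3 with limma-voom and 0 with DESeq2. EdgeR on the compared groups alone called 17, 8 higher and 9 lower, and without an expression filter 10, and 235 genes lay under an unadjusted p of 0.05. Hcn3, which overlaps the pyruvate kinase gene Pklr, had the smallest p, at 865 ± 497 CPM with VC against 5350 ± 1340 in the larger w12_WD libraries (n = 2; edgeR adjusted p = 0.0567 with all 3). Txnip stood at 1010 ± 840 against 56.9 ± 3.6 CPM (n = 2; 0.116) and the apolipoprotein gene Apoa4, which overlaps Gm47528, at 1560 ± 347 against 427 ± 136 (n = 2; 0.19). The fatty acid oxidation list was called as higher, with 0 of 16 past the gene test in both counts (camera 8.26e-05; 0.846 with an estimated correlation). The other list calls had 0 members past the gene test over all genes and an adjusted p of 0.846 with an estimated correlation. For the hepatocyte list, called as higher, 0 of 16 members passed in both counts and the median log2 change was 0.20, beside 0.102 over all genes (camera 0.0119). The call was lost without w12_WD 3 (0.202) or w12_WD+VC 3 (0.159) and its direction turned without w12_WD 2 (0.67). Wnt/beta-catenin targets were called as higher, with 1 of 5 adjusted over the list alone (camera 0.0206), lost without w12_WD 1 (0.13), w12_WD+VC 1 (0.235) or w12_WD+VC 3 (0.0733). Fatty acid and triglyceride synthesis was called as lower, with 0 of 17 in both counts (camera 0.025), and the acute-phase list as higher, with 1 of 12 adjusted over the list alone (0.0451). Without the 607-count library both were at 0.0543, and they were also lost without w12_WD 1 (synthesis, 0.633), w12_WD 2 (acute phase, 0.437), w12_WD+VC 1 (synthesis, 0.236), w12_WD+VC 2 (acute phase, 0.0941) and w12_WD+VC 3 (0.0737 and 0.147). Of these 5 list calls RLE kept that of fatty acid oxidation alone, with the others at 0.0566 to 0.0775. Gene calls numbered 1 without the 607-count library, 1 without w12_WD+VC 2 and 3 without w12_WD+VC 3.

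The diet by VC interaction at 12 weeks called 1 gene, Txnip. It stood at 205 ± 200 CPM in w12_CD, 36.5 ± 31.9 in w12_CD+VC, 56.9 ± 3.6 in the larger w12_WD libraries (n = 2) and 1010 ± 840 in w12_WD+VC (edgeR adjusted p = 0.0194). It was lost without w12_CD 2 (0.202), w12_CD+VC 1 (0.12), w12_CD+VC 2 (0.0983), w12_WD 1 (0.39), w12_WD 2 (0.434) or w12_WD+VC 1 (0.158), and also with RLE (0.057), DESeq2 (0.106) and limma-voom (0.101), whose 1 call was another gene. Apoa4 did not pass (0.0721), with 748 ± 547, 354 ± 192, 427 ± 136 (n = 2) and 1560 ± 347 CPM in the same order. Fatty acid oxidation genes had a more positive diet effect under VC, with 0 of 16 past the gene test and 2 adjusted over the list alone (camera 1.77e-06; 0.948 with an estimated correlation). Fatty acid and triglyceride synthesis had a more negative one, with 0 of 17 in both counts (camera 0.0325; 0.948 with an estimated correlation), lost without w12_WD 3, the 607-count library (0.068), and without w12_CD 2, w12_CD 3, w12_CD+VC 1, w12_CD+VC 2, w12_WD 1, w12_WD+VC 1 or w12_WD+VC 3 (0.051 to 0.597), as well as with RLE (0.0796) and class-wise scaling (0.0749). There were 3 calls without w12_CD 1 and 2 without w12_CD+VC 3.

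Between 12 weeks and 12 months on control diet, 3 of 10 male-biased liver genes fell, and 5 adjusted over the list alone (camera 2.95e-06; 0.309 with an estimated correlation). Serpina1e stood at 32.8 ± 12.3 CPM at 12 months against 418 ± 102 at 12 weeks (13.1-fold lower, edgeR adjusted p = 0.00215) and Mup7 at 16.7 ± 18.8 against 567 ± 248 (32.8-fold lower, 0.0066). Fads2 rose 4.79-fold, from 94.7 ± 51 to 449 ± 127 CPM (edgeR adjusted p = 0.000841), and the peroxisomal carnitine transferase Crot, which overlaps Gm37153, fell 6.77-fold, a call lost without m12_CD 3 (0.052). Tor1a rose 6.38-fold. Fatty acid and triglyceride synthesis was called as higher with 1 of 17 in both counts (camera 0.0192; 0.936 with an estimated correlation), lost without m12_CD 2 (0.0838), m12_CD 3 (0.266), w12_CD 2 (0.184) or w12_CD 3 (0.394) and with class-wise scaling (0.0627). Fatty acid oxidation was called as lower with 0 of 16 and 3 adjusted over the list alone (camera 0.00776; 0.936 with an estimated correlation), lost without m12_CD 1 (0.362). Hepatocyte genes were called as lower as a list, with 0 of 16 members past the gene test in both counts (camera 0.0441; 0.936 with an estimated correlation), lost without m12_CD 1 (0.92) or w12_CD 1 (0.949), with RLE (0.0918), with class-wise scaling (0.0864) and in 23 libraries (0.106). In all 68 genes were called, 29 higher and 39 lower, against 18 without m12_CD 3, 22 without w12_CD 2, 42 without m12_CD 1 and 45 without m12_CD 2. The split was 18 and 39 with RLE, 15 and 32 with DESeq2, and limma-voom called 154. The times differ in age, length of feeding and time since the inhalation sessions, and the labels give no batch. This contrast and the interactions with time cannot tell these apart.

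The diet effect without VC differed between 12 weeks and 12 months for 280 genes, 143 more positive and 137 more negative at 12 months, with the 607-count library among the 12-week samples. Maml1, which overlaps Gm26542, stood at 64.5 ± 35.8 CPM in w12_CD, 75.2 ± 25.8 in the larger w12_WD libraries (n = 2), 101 ± 13.7 in m12_CD and 6.49 ± 7.48 in m12_WD (edgeR adjusted p = 0.000847). Ackr2 stood at 56.2 ± 29.7, 61.2 ± 9.61 (n = 2) and 45 ± 10.5 CPM in the same order, with 0 counts in m12_WD (0.00217). Both kept the call without each library, and DESeq2 gave an adjusted p for 2 of the 12 named genes and called both. Lyz2 stood at 8.17 ± 4.68 CPM in w12_CD, with 0 counts in w12_WD, 3.34 ± 0.979 in m12_CD and 132 ± 102 in m12_WD (0.00997), lost without w12_WD 1 (0.059). All 9 called lists had a more positive diet effect at 12 months, with an adjusted p of 0.580 with an estimated correlation. Fatty acid oxidation had 6 of 16 and 9 adjusted over the list alone (camera 3.75e-07), hepatocyte genes 5 of 16 in both counts (3.75e-07), the stress response 2 of 14 and 6 (0.00304), VC metabolism and glutathione conjugation 3 of 18, or 7 and 1 in the other direction adjusted over the list alone (0.00305), and macrophage genes 1 of 10 in both counts (0.0264). Xenobiotic P450s had 1 of 11 and 2 adjusted over the list alone (camera 0.0264), lost without m12_CD 1 (0.0816) or m12_WD 1 (0.0803), and acute-phase genes 1 of 12 in both counts (0.0281), lost without m12_CD 3 (0.0653), m12_WD 2 (0.0579) or w12_WD 2 (0.0893). Glucose metabolism had 1 of 11 and 2 adjusted over the list alone (camera 0.0421) and NRF2 targets 2 of 8 and 3 (0.0453), each lost without m12_CD 1, m12_WD 1, m12_WD 2, w12_CD 1, w12_WD 2 or the 607-count library (0.0584 to 0.286 and 0.0629 to 0.111). RLE kept 4 of the 9 calls and ended those of macrophage genes and xenobiotic P450s (0.078 each), acute-phase genes (0.0916), glucose metabolism (0.106) and NRF2 targets (0.123). Class-wise scaling kept 6 and ended those of acute-phase genes (0.0541), glucose metabolism (0.0644) and NRF2 targets (0.0651). Median log2 differences were 0.594 in genes without an overlap and -0.114 in genes with one, beside no-overlap shares of 25.9% in m12_WD and 15.6% in m12_CD. Counts were 45 without w12_WD 2, 144 without w12_CD 1, 148 without w12_CD 2, 160 without m12_CD 1 and 310 without the 607-count library. More positive and more negative genes numbered 209 and 74 with RLE, 112 and 50 with DESeq2, 91 and 139 with class-wise scaling and 131 and 179 in 23 libraries.

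The VC effect on Western diet differed between 12 weeks and 12 months for 7 genes, all more positive at 12 months. Zfhx2os stood at 590 ± 18.2 CPM in the larger w12_WD libraries (n = 2), 478 ± 136 in w12_WD+VC, 29.9 ± 7.21 in m12_WD and 262 ± 107 in m12_WD+VC (edgeR adjusted p = 0.000871) and kept the call without each library. Zfp668, at 104 ± 39.3 (n = 2), 92.9 ± 34.6, 0.63 ± 1.09 and 40.3 ± 23.2 CPM in the same order (edgeR adjusted p = 0.00237), lost it without w12_WD 1 (0.0521) and with limma-voom (0.0834). Hcn3, which overlaps Pklr, passed at 0.0323, and lost the call without w12_WD 1, w12_WD 2, w12_WD+VC 1, w12_WD+VC 3, m12_WD 1 or m12_WD+VC 3 (0.0502 to 0.24), with RLE (0.0687) and with DESeq2 (0.0666). All 4 called lists were more negative at 12 months. Fatty acid oxidation had 0 of 16 and 7 adjusted over the list alone (camera 1.73e-08; 0.687 with an estimated correlation) and hepatocyte genes 0 of 16 and 3 (8.82e-07; 0.687). Wnt targets had 0 of 5 and 1 adjusted over the list alone (camera 0.0208; 0.687 with an estimated correlation), lost without m12_WD 1 (0.0639), w12_WD 1 (0.0505) or w12_WD+VC 1 (0.0527). Acute-phase genes had 0 of 12 and 1 (camera 0.0382; 0.765 with an estimated correlation), lost without m12_WD 1, m12_WD 2, m12_WD+VC 3, w12_WD 2, w12_WD+VC 2 or w12_WD+VC 3 (0.0581 to 0.366), with class-wise scaling (0.112) and with RLE (0.0578). Median log2 differences were -0.406 in genes without an overlap and 0.034 in genes with one, beside no-overlap shares of 20.7% in m12_WD+VC and 25.9% in m12_WD. Counts were 2 without w12_WD 1, 3 without w12_WD 2, w12_WD+VC 1 or m12_WD+VC 3, 4 without m12_WD 1 and 11 without m12_WD 2.

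Genes of RNA methylation and of liver tumours were fixed for report in every comparison. The m6A writer Mettl3 had 1262 counts in 23 libraries, and its log2 changes ran from -0.52 to 0.17 over the 9 comparisons of groups, with edgeR adjusted p from 0.543 to 1. The eraser Alkbh5 had 142 counts and adjusted p from 0.594 to 1. The fetal liver gene Afp had 597 counts, and log2 changes from -1.32 to 0.73 (adjusted p 0.0667 to 1). Too few counts were found to test Fto (55 counts in 17 libraries), Ythdf2 (44 in 15), the proliferation marker Mki67 (17 in 9) and the liver tumour marker Gpc3 (1 in 1). Changes in these 4 genes were not detectable at this depth.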

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

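The tests of technical explanations in this part were chosen only after the results were seen, as was the look at the spread within splits, while the splits of libraries were planned. A test of the difference between effects found genes in 4 places. The diet by VC interaction called 1 gene at 12 weeks and 412 at 12 months, the diet by time interaction called 280, and the VC by time interaction on Western diet called 7.

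Other splits of the same libraries were counted. For the interaction at 12 weeks, 17 of 100 drawn splits gave at least as many genes, the highest other split 10, so chance cannot be excluded. At 12 months 2 of 100 splits gave as many as the real 412, the highest other also 412. For diet by time 4 of 100 gave as many as the real 280, and the highest other gave 584. For VC by time 2 of 100 gave as many as the real 7, the highest other 8. These last 3 shares are under 0.05 but leave open whether chance can be excluded. Every other split that reached the real count kept 1 arm, 1 of 20, 3 of 18 and 1 of 21 such splits in the order given, and these still hold the real effect of that arm. Splits that regrouped both arms put main effects into the spread within groups, with a median biological coefficient of variation of 0.358, 0.384 and 0.332 against 0.317 in the real split, and 0 of 79, 0 of 81 and 0 of 78 reached the real count. Comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. Real counts and highest others were 1 and 1 for diet without VC at 12 weeks (3 of 10 as large), 22 and 3 for diet with VC, 0 and 2 for VC on control diet and 0 and 1 for VC on Western diet (10 of 10 each). At 12 months they were 1028 and 3, 76 and 0, 219 and 1, and 24 and 0 in the same order, and 68 and 5 for time. In these and in diet with VC at 12 weeks the real split was the 1 with the highest count. Their regrouped splits also put the group difference into the spread within groups. The median biological coefficient of variation was 0.383, 0.34, 0.35 and 0.329 at 12 months, 0.335 for time and 0.33 for diet with VC at 12 weeks, against 0.317 in the real split. The gap between real and other counts is therefore no measure of support.

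Most counts lay in entries whose exons overlap a gene on the other strand, 78.57% of counts against 23.75% of entries. Counting without strand, with the other entries keeping all their reads, would leave albumin among the first 5 entries, yet Alb ranked 20. Counting of the strand opposite to each gene remains open for every entry: 25 of the 30 entries with most counts overlap a gene on the other strand, such as Gm30505 with 811098 counts against 9493 for Ahsg and Tomm40l with 195875 against 575 for Nr1i3. Among liver genes of the lists with such an overlap, the partner entry held more counts in 56.2% of 16 pairs (exact 95% interval 29.9% to 80.2%, two-sided exact binomial p = 0.804). The median ratio of partner to gene was 2.47 and the mean log2 ratio 1.09 ± 4.38 (SD over pairs, two-sided exact sign-flip p = 0.333). These tests cannot decide whether the opposite strand was counted. Totals were taken over whole entries, while the shared exons ran from 30 bp (Me1) to 3304 bp (Nr1i3). The kit named in the labels does not mark strand, whereas counting of the opposite strand needs libraries that do. The unlike counts of such pairs leave open whether these libraries mark strand, and no biological explanation was tested.

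VC on control diet at 12 months gave 172 higher against 47 lower genes, 133 and 8 without an overlap and 39 and 38 with one. Without m12_CD+VC 3 the lean was absent (170 higher, 176 lower), and no gene was called without m12_CD 1 or without m12_CD+VC 2, the libraries with the lowest and the highest no-overlap share (11.56% and 31.63%). A difference in library size is argued against as the whole cause, since with every larger library thinned to 126160 counts a median of 86% of the 100 to 154 calls were higher over 20 draws (79.9% to 91.3%, lowest exact 95% bound 72.7%, taking genes as independent). A larger share of no-overlap entries in exposed libraries stays open, since with 1 scaling factor per class 69.2% of 107 calls were higher (exact 95% interval 59.5% to 77.7%, taking genes as independent), which reaches the bound of 60% set for that cause, and no-overlap genes tested alone gave 10 higher and 8 lower. An effect of the exposure also stays open and was not tested.

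Macrophage markers were higher on Western diet without VC at 12 months, with 6 of 10 past the gene test. The shift of no-overlap entries is argued against as the whole cause by the 5 members still called with class-wise scaling, although the list call there holds only with the preset correlation (camera 0.000398; 0.295 with an estimated correlation). A lower share of hepatocyte RNA was predicted to raise endothelial and stellate markers alike and to put the hepatocyte median below 0. The 12 endothelial and stellate markers had a median log2 change of 1.02, with 10 above 0. The macrophage median lay 1 log2 unit above theirs (two-sided permutation test over genes with 100000 draws, p = 0.135), or 0.53 with class-wise scaling (p = 0.344). Hepatocyte genes, 15 of 16 of them without an overlap, had a median log2 change of 0.69, so that part of the prediction failed. With class-wise scaling it was 0.31, and the list was not called (camera 0.102). The hepatocyte median cannot decide the cause, since changes are relative to a bulk of genes that includes hepatocyte RNA. Genes without an overlap also had a median of 0.475 as a class. A lower share of hepatocyte RNA therefore stays open. More macrophages, or more of these transcripts per cell, may account for the pattern as a hypothesis if the entries count their own genes, which these libraries cannot separate.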

How the results depend on the processing

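Class-wise scaling, the no-overlap test and the 23-library fit were chosen after seeing the data. The planned use of the series table in place of the per-sample files was not run, as the per-sample files hold scaled log2 values of those counts. Of 172 named calls, 152 kept their direction and side of the threshold with RLE, 150 with no filter, 115 of 136 with DESeq2, which gave no adjusted p for the other 36, 133 with limma-voom, 137 with class-wise scaling, 158 in 23 libraries, 116 of 139 with the compared groups alone, 111 of 127 with the same time alone and 78 of 114 among no-overlap genes. Leaving out 1 library kept 800 of 1212 values, and 0 turned. Of 72 list calls, 52 were kept with RLE, 57 with class-wise scaling, 65 in 23 libraries, 491 of 588 leaving out 1 library and 0 with an estimated correlation. Where a count moved, the cause was not tested, except that the no-overlap and compared-group fits hold fewer genes or samples. RLE and DESeq2 both take size factors from genes above 0 in every library, at most 270, so they are not separate checks of scaling. For VC on control diet at 12 months they shifted log2 changes by a median of 0.417 and 0.436. Depth limits low genes, as a count of 0 allows up to 3.12 to 23.78 CPM in the 23 larger libraries.

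Counts of calls that moved by over 1.5 times are given by setting. Without a filter there were 6 for diet without VC at 12 weeks, 41 for diet with VC, 5 for VC on control diet, 10 for VC on Western diet and 7 for the interaction. At 12 months there were 103 for VC on control diet and 232 for the interaction, and 18 for VC by time. With RLE there were 0 for the interaction at 12 weeks, 46 for diet with VC and 442 for VC on control diet at 12 months, and 4 for VC by time. DESeq2 gave 0 for diet without VC and 0 for the interaction at 12 weeks, 44 for diet with VC, 14 for VC on Western diet and 252 for the interaction at 12 months, 162 for diet by time and 3 for VC by time. Limma-voom gave 6 for diet without VC, 40 for diet with VC and 3 for VC on Western diet at 12 weeks, 159 for diet with VC and 134 for VC on control diet at 12 months, 154 for time and 16 for VC by time.

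The compared groups alone gave 6 for diet without VC, 13 for diet with VC and 17 for VC on Western diet at 12 weeks. At 12 months they gave 610, 158, 73 and 11 for diet without VC, diet with VC, VC on control diet and VC on Western diet, then 40 for time, 186 for diet by time and 13 for VC by time. The same time point alone gave 0 for diet without VC at 12 weeks and 10 for VC on Western diet at 12 months. Class-wise scaling gave 1 for VC on control diet at 12 weeks, 107 for it at 12 months and 251 for the interaction. No-overlap genes alone gave 0 for diet without VC, 6 for diet with VC, 1 for VC on control diet and 0 for the interaction at 12 weeks. At 12 months they gave 370, 35, 18, 9 and 129 in the order diet without VC, diet with VC, VC on control diet, VC on Western diet and interaction, then 21 for time, 82 for diet by time and 0 for VC by time. In 23 libraries there was 1 for VC on Western diet at 12 weeks.

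Leaving out 1 library gave ranges of 0 to 1 for diet without VC, 0 to 42 for diet with VC, 0 to 1 for VC on control diet, 0 to 3 for VC on Western diet and 0 to 3 for the interaction at 12 weeks. At 12 months the ranges were 632 to 1056, 2 to 73, 0 to 346, 10 to 19 and 99 to 644 in that order, then 18 to 72 for time, 45 to 356 for diet by time and 2 to 11 for VC by time. The ends came without m12_CD 1 and m12_WD 3 for diet without VC at 12 months, m12_WD+VC 2 and m12_CD+VC 1 for diet with VC, m12_CD 1 (also m12_CD+VC 2) and m12_CD+VC 3 for VC on control diet, and m12_WD+VC 3 and m12_WD 3 for the interaction. The hepatocyte list in VC on Western diet at 12 weeks ranged from an adjusted p of 6.08e-12 without w12_WD 1 to 0.67 in the other direction without w12_WD 2.

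The Pearson correlations of log2 changes across genes, leaving out 1 library, ranged from -0.043 to 0.013 between the VC effects on both diets at 12 weeks and from -0.419 to -0.183 at 12 months. Between the diet effects without and with VC they ranged from 0.078 to 0.216 at 12 weeks and from 0.07 to 0.256 at 12 months. Between the times they ranged from -0.221 to 0.108 for diet without VC, 0.144 to 0.325 for diet with VC, -0.152 to 0.19 for VC on control diet and -0.197 to -0.031 for VC on Western diet.

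The replicate numbers did not clearly pair the libraries. Correlations of same-numbered libraries ran from -0.196 to 0.152 at 12 weeks (median 0.024, 2 of 18 over 0.1) and from -0.198 to 0.184 at 12 months (median 0.078, 6 of 18). For libraries with other numbers the medians were -0.005 (5 of 36 over 0.1) and -0.019 (7 of 36). At the 2 times, 4 of 12 and 5 of 12 libraries correlated best with their own number. A weak pairing at 12 months is not excluded. With the replicate block, counts moved by over 1.5 times to 0 for diet without VC at 12 weeks, 1 for VC on Western diet at 12 weeks, 40 for it at 12 months and 14 for VC by time. The block kept 160 of 172 named calls, 8 of 15 in the time effect, and 66 of 72 list calls, and fatty acid and triglyceride synthesis turned direction in the time effect (adjusted p = 0.606).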

Other observations

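The views in this part were chosen only after the results were seen, apart from the gene lists. Counts were also summed by the gene that each entry overlaps on the other strand, which gave 5438 names, 2070 of them tested. This view is a description, since the strand setting of the counting is not known. Over the 13 comparisons, 7 of 117 list tests with 9 lists were called by camera, and 1 held with an estimated correlation. That was fatty acid and triglyceride synthesis with 3 members, lower with VC on Western diet at 12 weeks (camera adjusted p = 0.000882; 0.0368 with an estimated correlation), with 0 members past the gene test. In 23 libraries it stood at 0.000665 and 0.0428, and no other library was left out in this view. The same list was lower for diet with VC at 12 months (camera 0.0297; 0.171 with an estimated correlation) and higher with time (0.00789; 0.103). It was more negative in the interaction at 12 weeks (camera 0.0035; 0.072 with an estimated correlation) and in diet by time (0.00892; 0.125). Cholesterol biosynthesis with 3 members was lower for diet with VC at 12 months (camera 0.00921; 0.0794 with an estimated correlation) and higher with time (0.023; 0.104).

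For diet without VC at 12 months neither list was called in this view (camera 0.192 each; 0.515 with an estimated correlation). The cholesterol members, chosen after their values were seen, went both ways, with Lss at -3.56 on the log2 scale (edgeR adjusted p = 1.2e-07), Cyp51 at -1.72 (0.0104, from Akap9) and Fdft1 at 1.33 (0.0226, from Ctsb). Of the fatty acid list 1 of 3 passed, Acss2 at -3.95 (edgeR adjusted p = 5.04e-07, from Acss2os, Ggt7 and Gss).

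Of the tested lists, 11 were called in no comparison. Their smallest camera adjusted p was 0.126 for lipid droplet and lipid uptake, 0.136 for nuclear-retained RNA, 0.14 for endothelial cell, 0.145 for stellate cell and fibrosis, 0.178 for interferon response and 0.189 for core clock. It was 0.226 for other RNA modification enzymes, 0.28 for proliferation, 0.308 for base excision and direct DNA repair, and 0.334 for m6A enzymes and readers and for immediate early genes. A further 13 lists had too few tested members. These were p53 targets, oncofetal markers, inflammatory cytokines and NF-kB targets and female-biased genes with 2 each, B and plasma cell, cholangiocyte, erythroid and exocrine pancreas with 1 each, and T and NK cell, neutrophil, adipose tissue, skeletal muscle and mitochondrially encoded respiratory chain with 0.

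Pearson correlations of log2 changes were taken across the 4198 genes, which are not independent replicates, with Spearman values in brackets. The VC effects on control diet and on Western diet correlated at -0.327 (-0.372) at 12 months and -0.012 (0.028) at 12 weeks. Diet effects without and with VC correlated at 0.174 (0.028) at 12 months and 0.203 (0.211) at 12 weeks. By rank, the diet effects at 12 months thus hardly correlated. Between the times, the correlation was -0.001 (-0.054) for diet without VC and 0.26 (0.188) for diet with VC. It was -0.002 (0.044) for VC on control diet and -0.12 (-0.115) for VC on Western diet. These 8 pairs of effects were computed as 1 family and have no p-value.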
